A study of Homo sapiens with 6 samples.

How the data were processed

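Messenger RNA of JAR cells was sequenced in 6 libraries, 3 of parental cells and 3 of cells selected for resistance to methotrexate (MTX). Per the labels, selection started at 10 nM MTX, and the dose was raised in steps for months, the cells were grown in RPMI-1640 with serum, total RNA was extracted with a column kit and the libraries were sequenced as read pairs. The deposited values are transcripts per 1000000 (TPM), which the authors obtained with kallisto on GRCh38, per the submitters' processing notes. TPM divides each transcript's estimated reads by its length and scales every library to the same sum. The kallisto version, the transcript annotation release, the strand setting and any read filter are not given in the sources used here. TPM keeps no read depth, so the depth of each library is unknown, and no interval or detection limit that needs counts is given. In the file each library summed to 1000000 TPM when every distinct transcript was counted 1 time, which was checked for all 6 libraries.

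The deposited table had 193845 lines for 191887 distinct Ensembl transcripts. The 1958 lines that repeated a transcript were left out, and 19 transcripts paired with more than 1 symbol kept the first. Transcript values were summed per gene symbol, which gave 28909 symbols, of which 28881 had coordinates in GENCODE release 29. Of the distinct transcripts, 88% were in that release. The 9542 transcripts with no symbol held 0.750% to 0.879% of the TPM of a library and were tested apart from the genes.

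Genes with a mean of at least 1 TPM over the 6 libraries were tested, 11657 in all, of which 11242 are protein-coding. The values were taken as log2(TPM + 1), so that log2 fold changes of genes with low TPM are understated. Resistant and parental libraries were compared by limma (moderated test, eBayes with a trend of variance on level), with Benjamini-Hochberg adjustment over all tested genes. A gene was counted as changed at an adjusted p under 0.05, and a separate count also required a change of at least 2-fold on that scale. Below, fold changes are resistant over parental, levels are means ± SD over 3 libraries, and "rose" and "fell" are used for an adjusted p under 0.05.

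The labels give each library a batch number from 1 to 3 that is shared between the groups, so that each batch holds 1 library of each group. Deviations from the group means, correlated across genes between the parental and resistant libraries of equal number, gave 0.0334, -0.0432 and -0.0208 for batches 1, 2 and 3. The comparison was made without the batch number, as set in advance, and a fit with it as a term was run as an alternative. The labels do not say whether the 3 libraries of a group came from separate cultures. If they did not, the p-values measure the spread between these libraries alone. No independent selections are named either, so even with separate cultures the p-values do not measure how much selections differ. The comparison cannot tell an effect of MTX apart from other changes of the cells during the selection. The labels also do not say whether MTX was in the medium at harvest.

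Gene lists and chromosome bins were compared with all other tested genes by camera (limma, preset inter-gene correlation of 0.01), with adjustment over the lists or over the bins. Before the data were examined, 50 lists of folate, drug transport, trophoblast, metabolic, cell cycle, stress, immune, matrix and signalling genes and of markers of other cell types were fixed, of which 45 had at least 5 tested members. Bins were 10 Mb long, and the 281 bins with at least 10 tested genes were tested. Counts of list members are given over all genes tested and adjusted over the list alone. Chromosome segments wider or narrower than the bins were drawn after the data were seen. For near-identical genes, the share of a gene's sequences of 31 bases that also occurs in another gene was counted in the GENCODE transcripts for 189 genes. Below, this share is printed for some genes only. It was, for example, also 60.8% for SLC46A1, 35.7% for PGAM1, 31.7% for TAP2, 31.4% for LDHB, 23.8% for DHFR and 19.5% for MDM2.

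Named genes followed a rule set before the data were examined. They were 15 antifolate genes and CGA whatever their result, the 10 protein-coding genes with the largest rise and the 10 with the largest fall among genes with an adjusted p under 0.05, no overlap between groups and at least 5 TPM in the higher group, and up to 4 members per described list with the smallest adjusted p. Other genes are marked as chosen after their values were seen. A sum over several genes was compared by an exact two-sided permutation test of 3 against 3 libraries, which cannot give a p under 0.1.

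Alternatives were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 TPM, median-ratio scaling, quantile normalization, protein-coding genes only, mitochondrially encoded genes left out, eBayes without trend or with robust hyperparameters, the batch number as a term, each library left out in turn, camera with an estimated correlation, fry, 5-Mb bins and DHFR summed with its pseudogenes. Leaving the genes of the shifted bins out of the lists was added after seeing the data, as were the alternatives for genes named outside the rule. The procedure was tested on simulated data with the observed levels and spreads of the 11657 genes and 200 changed genes. It recovered 25 of 50 genes changed by 0.5 on the log2 scale, 45 of 50 changed by 1, 49 of 50 changed by 1.5 and 48 of 50 changed by 2. It called 7 unchanged genes, none of them at 2-fold. A simulated list and a simulated bin shifted by 0.3 were recovered, with 0 of the other lists and 0 of the other bins called by camera. The simulated genes were drawn independently of each other. The simulation therefore does not show how often camera calls an unshifted set whose members are correlated, as in the real data. The tools were R 4.3.3 with limma 3.58.1 and the data.table package (1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Sex-linked marker genes were not described.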

Results

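Gene expression was measured by messenger RNA sequencing in JAR cells, a human choriocarcinoma line of trophoblast origin that makes the placental hormone hCG. There were 3 libraries of parental cells and 3 of cells that had been selected in stepwise rising concentrations of methotrexate (MTX), an antifolate drug that inhibits dihydrofolate reductase. The values are TPM for each library, and the depth of the libraries is unknown because TPM keeps no counts. Between 11550 and 11724 genes reached 1 TPM in a library. Correlations between libraries across genes were 0.991 to 0.993 within a group and 0.979 to 0.982 between the groups. Mitochondrially encoded messenger RNA took 4.98%, 4.34% and 6.02% of TPM in parental libraries 1, 2 and 3 and 5.57%, 8.13% and 7.30% in resistant libraries 1, 2 and 3. The 10 genes with the most TPM took 9.52% to 10.1% in parental and 11.4% to 12.2% in resistant libraries.

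The comparison of resistant with parental cells addresses how gene expression differs after the selection, without telling MTX apart from other changes of the cells during it. DHFR, the gene of the enzyme that MTX inhibits, stood at 37.2 ± 2.54 TPM in parental and 1257 ± 75.5 TPM in resistant cells, a 33.8-fold difference. Its neighbours on the long arm of chromosome 5 rose with it, while many genes of the arm beyond them fell by small amounts. Among the protein-coding neighbours, the mismatch repair gene MSH3 rose most. 4 genes of the hCG beta subunit fell, and the summed level of its 6 genes was 6.08-fold lower. By small amounts, 22 of 34 tested genes of glycolysis and hypoxia fell, as did 34 of 72 of the nuclear-encoded respiratory chain and 15 of 36 of mitosis, while 9 of 30 genes of epithelial junctions rose. No list was called with an estimated correlation (lowest adjusted p = 0.106), with 4235 genes at an unadjusted limma p under 0.05. Transcripts of the folate carriers and of the enzymes that add or remove polyglutamate on antifolates did not pass the test.

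DHFR lies on chromosome 5 from 80626228 to 80654983 (GRCh38). The log2 fold change was 5.04 (SE 0.06, limma adjusted p = 1.21e-09), and the differences within batches 1, 2 and 3 were 4.97, 5.24 and 4.92, each from 1 library per group. DHFR levels in parental libraries were 39.0, 34.3 and 38.2 TPM, against 1251, 1336 and 1186 TPM in resistant libraries. The share of DHFR TPM held by its main transcript, ENST00000439211, was 79.1% ± 0.282 in parental and 80.5% ± 1.37 in resistant cells. DHFRP1, a processed pseudogene of DHFR on chromosome 18, went from 19.98 to 608.5 TPM, but 100% of its sequences of 31 bases occur in DHFR, so its own level is uncertain. DHFR summed with its processed pseudogenes was 57.2 ± 7.38 TPM in parental and 1866 ± 100 TPM in resistant cells, 32.7-fold apart.

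The rise extended over the neighbours of DHFR, and its size was lower with distance from DHFR towards the telomere (Spearman's rho -0.94 across 12 genes between bounds drawn after the data were seen, which are not independent replicates). MSH3 starts beside DHFR on the opposite strand, at 80654648, and shares 336 bp with it, in which the division of reads is unknown without the strand setting. It rose 32.8-fold, from 9.54 ± 0.154 to 312.7 ± 7.75 TPM (adjusted p = 3.21e-10), a fold that is uncertain to that extent. RASGRF2, an exchange factor for RAS and RAC proteins, rose 11.8-fold to 196.7 ± 7.17 TPM and ZCCHC9 rose 9.47-fold to 334.6 ± 9.60 TPM. CKMT2, the creatine kinase of muscle mitochondria, went from 0.592 ± 0.254 to 9.80 ± 1.28 TPM. SSBP2 rose 5.37-fold and TMEM167A rose 5.01-fold. RPS23, a ribosomal protein gene that overlaps the end of ATG10 and shares 12.8% of its sequences of 31 bases with other genes, rose 4.61-fold from 4817 ± 144 to 22212 ± 1939 TPM. The following 5 genes of the region were chosen after their values were seen. XRCC4, a factor of DNA end joining whose annotated start overlaps TMEM167A, rose 3.50-fold, and HAPLN1 at 83637805 to 83721613 rose 2.74-fold. ATG10 rose 4.78-fold. FAM151B, on the centromeric side of DHFR, rose 1.54-fold (adjusted p = 0.0314), a call lost with no filter (0.105) and without parental library 1 (0.0667), parental library 3 (0.0755), resistant library 1 (0.105) or resistant library 2 (0.0853). DBIP2, a pseudogene between FAM151B and DHFR, was listed at 0 in parental cells and at 10.6 ± 1.97 TPM in resistant cells.

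**Figure D1:**
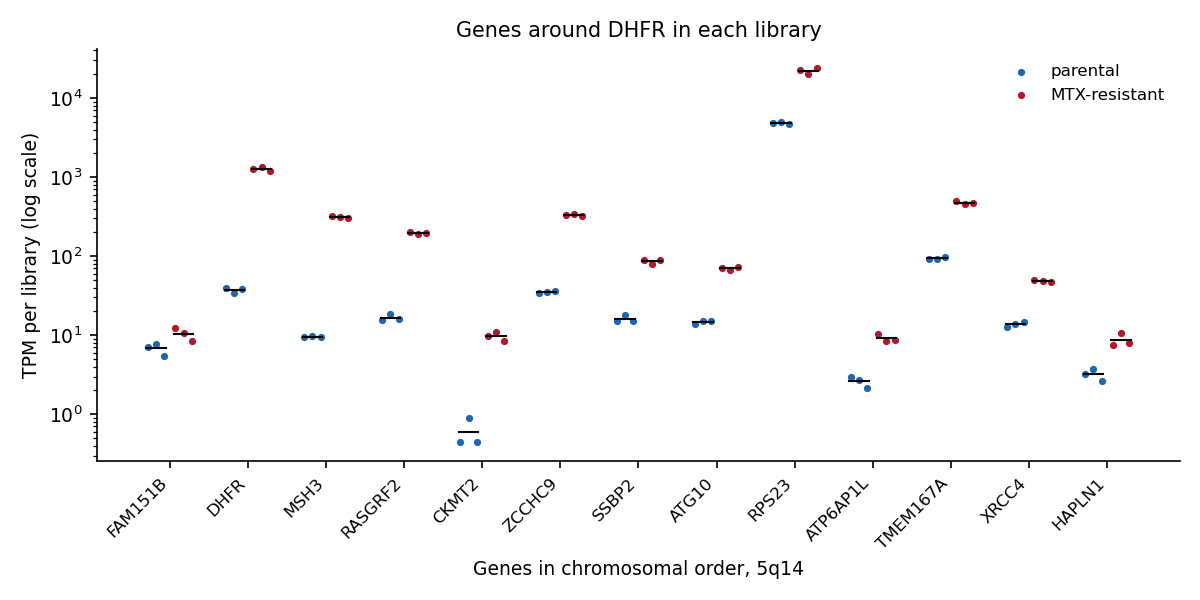
TPM of 13 genes from 80.5 to 84 Mb of chromosome 5 in each library (log scale), in chromosomal order, with parental libraries in blue, resistant libraries in red and a bar at the mean of each group. DHFR and MSH3 have the widest gap between groups, and HAPLN1 at the telomeric end has a 2.74-fold gap.

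Of the 35 genes listed in advance around DHFR, 27 were tested, of which 21 rose, 1 fell and 5 did not pass. Adjusted over the list alone, 23 were higher and 1 was lower. The list was shifted up (median log2 fold change 0.83, camera adjusted p = 1.54e-19, with adjusted p = 0.106 with an estimated correlation). On the centromeric side SERINC5 rose from 6.44 ± 0.0290 to 13.2 ± 0.639 TPM and LHFPL2 from 14.05 ± 0.405 to 25.8 ± 1.57 TPM, both chosen after their values were seen. COX7C, a subunit gene of cytochrome c oxidase on the telomeric side, was the member that fell, from 1132 ± 70.9 to 720.0 ± 17 TPM.

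Seen along the whole chromosome, the direction turned at about 84 Mb, beyond HAPLN1. In the segment from 80.5 to 84 Mb all 14 tested genes rose, 13 of them at least 2-fold, with a median log2 fold change of 2.33 (13 or 14 genes rose when any 1 library was left out). From 50 to 80.5 Mb, 53 of 103 tested genes rose and 2 fell, with a median of 0.31. From 84 Mb to the end of the arm, 175 of 312 tested genes fell and 3 rose, with a median of -0.33. Those 3 were 0 without parental library 1 or resistant library 1, and 1 without parental library 2 or resistant library 3. Genes of the short arm and around the centromere had a median of 0.04. SPARC, a matrix glycoprotein gene of the distal part, fell from 226.6 ± 11.5 to 106.1 ± 10.9 TPM, and ERAP1, a peptidase that trims antigens, fell from 6.49 ± 1.11 to 2.48 ± 0.332 TPM. NUDT12, chosen after its values were seen, went from 4.47 ± 0.265 TPM to a listed value of 0 in all 3 resistant libraries.

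**Figure D2:**
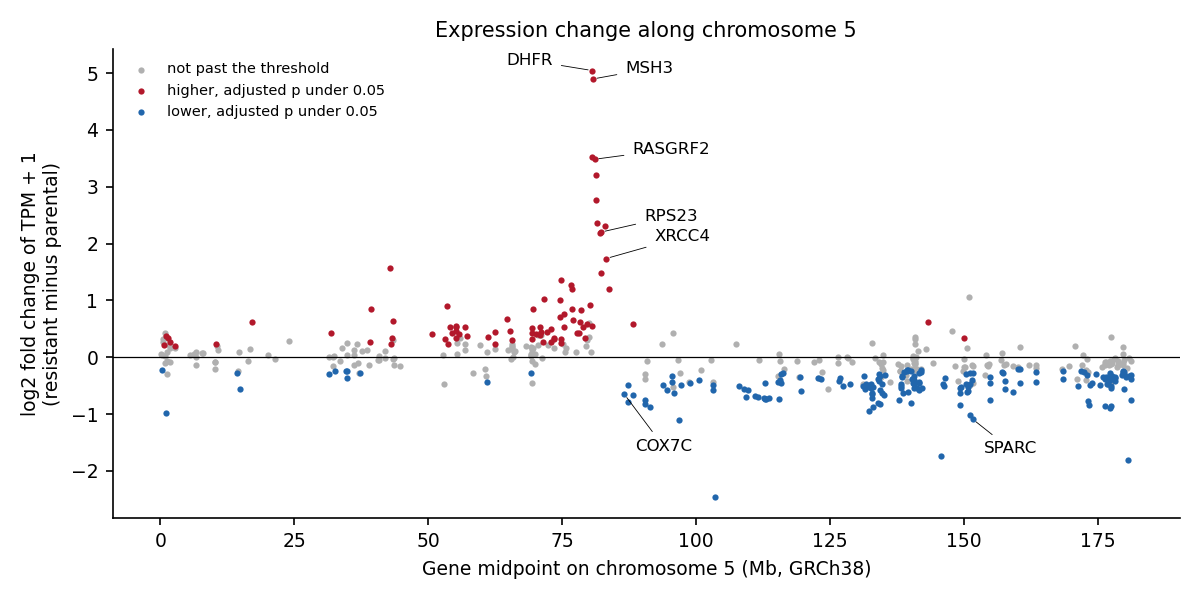
Log2 fold change (resistant minus parental) of each tested gene of chromosome 5 at its midpoint in Mb (GRCh38), in red or blue where the adjusted p was under 0.05 and grey elsewhere. The values peak at DHFR (5.04) and lie mostly below 0 from 84 Mb to the end of the arm.

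Chromosomes 12 and 20 had blocks of lower expression. In the segment from 64 to 86 Mb of chromosome 12, 39 of 61 tested genes fell and 1 rose, 11 fell at least 2-fold, and the median log2 fold change was -0.59. The riser was not called without parental library 2 or 3 or resistant library 1 or 2, which gave a count of 0, and there were 2 without parental library 1. MDM2, the ubiquitin ligase that restrains p53, lies there (68808176 to 68850686) and fell from 411.7 ± 8.66 to 170.6 ± 8.94 TPM (adjusted p = 2.08e-06). Its neighbours NUP107 and RAP1B fell by 1.09 and fell by 1.05 on the log2 scale, and PAWR, a proapoptotic gene at 79574979 to 79691097, fell from 403.5 ± 8.45 to 160.7 ± 6.5 TPM. CPSF6, which lies between these at 69239537 to 69274358, stood at 70.9 ± 8.36 and 75.3 ± 4.45 TPM (adjusted p = 0.484). On the short arm, 11 of 17 tested genes from 15 to 25 Mb fell, LDHB among them, and CDKN1B, the gene of the cell cycle inhibitor p27 at 12715058 to 12722371, fell from 236.6 ± 16.4 to 106.7 ± 4.62 TPM. Except for MDM2 and LDHB, these genes of chromosome 12 were chosen after their values were seen. On the long arm of chromosome 20, 99 of 210 tested genes fell and 15 rose (8 without resistant library 1, 9 without resistant library 2 and 9 without resistant library 3), with a median of -0.27. The short arm of chromosome 20 had a median of 0.06.

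**Figure D3:**
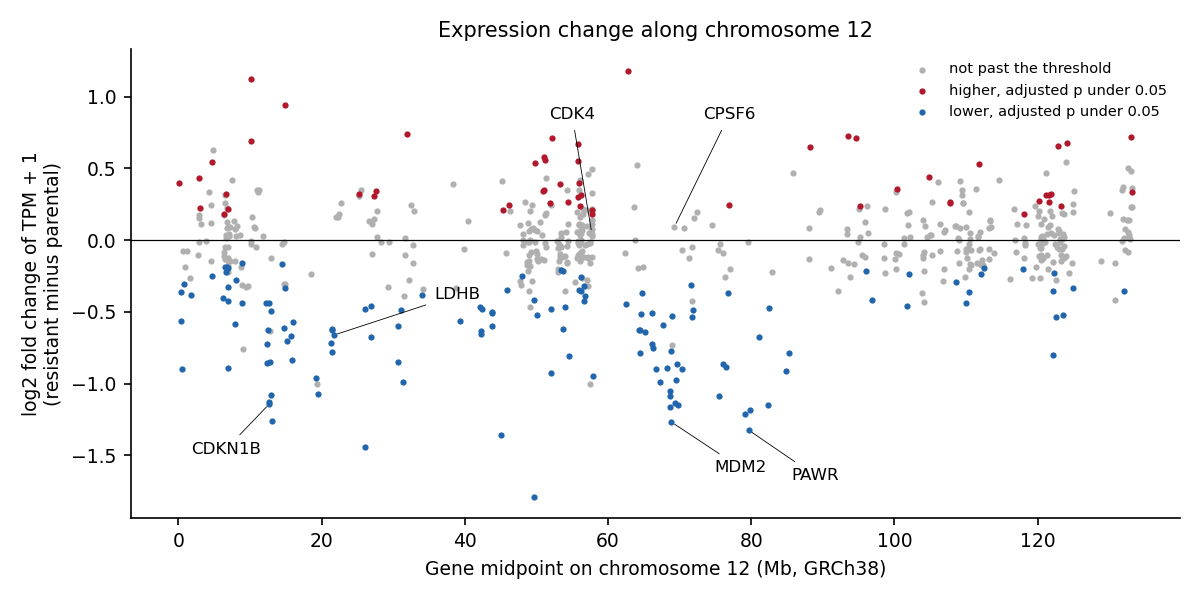
Log2 fold change of each tested gene of chromosome 12 at its midpoint in Mb (GRCh38), with genes at an adjusted p under 0.05 in red or blue. Genes between 64 and 86 Mb, such as MDM2 and PAWR, lie mostly below 0, with CPSF6 near 0 among them.

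Of the 281 bins of 10 Mb, 25 were shifted by camera, 6 up and 19 down, of which 12 lay on chromosome 5, 4 on chromosome 20, 3 on chromosome 12 and 2 on chromosome 3. With an estimated correlation no bin was shifted (lowest adjusted p = 0.181), although 4235 genes had an unadjusted limma p under 0.05. The shifted bins held 870 of the tested genes (7.46%), and 44 of the genes changed at least 2-fold (25.9%). They also held 475 of the genes changed at any size (17.7%). Below, the location is printed for some genes only, so a gene named without one may also lie in a shifted bin.

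Over all 11657 tested genes, 93 rose and 77 fell at least 2-fold. The groups did not overlap for any of these 170 genes, and for 40.5% of all tested genes, where chance gives 10%. At any size 1369 genes rose and 1318 fell. With mitochondrially encoded genes left out and TPM rescaled, 1555 rose and 1126 fell, so that this balance depends on the scaling. Without resistant library 1 the count of genes that rose was 789, and without parental library 1 it was 887, with 851 that fell. The median log2 fold change of all tested genes was 0.01. Chromosome 5 held 19 of the genes that rose at least 2-fold, and chromosome 12 held 19 of those that fell.

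Among protein-coding genes that passed the test without overlap between the groups and with at least 5 TPM in the higher group, the largest rises outside the DHFR region were those of DMKN, GNRH2 and FABP7. DMKN, which encodes a secreted epidermal protein, went from 2.32 ± 0.0656 to 25.6 ± 0.757 TPM (adjusted p = 2.18e-07). GNRH2, a gene of a gonadotropin-releasing hormone, went from 3.63 ± 0.918 to 26.3 ± 3.88 TPM, and FABP7, a fatty acid binding protein gene, from 10.5 ± 2.59 to 61.7 ± 5.59 TPM. Their largest fall was that of LIPA, the lysosomal acid lipase gene (chromosome 10, 89213569 to 89414557), from 11.8 ± 0.526 to 0.140 ± 0.141 TPM (adjusted p = 1.46e-06). It was the only gene with at least 5 TPM in parental cells and under 0.5 TPM in every resistant library. RAB40B fell from 8.20 ± 0.231 to 0.312 ± 0.216 TPM. ASS1, the argininosuccinate synthase of arginine synthesis, fell from 20.1 ± 1.38 to 2.85 ± 0.131 TPM, with 19.2% of its sequences of 31 bases shared with other genes. MBNL3, a splicing regulator gene, fell from 16.7 ± 1.85 to 3.27 ± 0.385 TPM, and FN1, the fibronectin gene, from 6.07 ± 0.217 to 0.976 ± 0.584 TPM. TMEM179, the phosphatase gene ACP5 and APLP1 fell by 1.93, fell by 1.81 and fell by 1.70 on the log2 scale.

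The folate carrier gene SLC19A1 stood at 12.5 ± 1.75 and 11.7 ± 0.501 TPM in parental and resistant cells, SLC46A1 at 4.96 ± 0.786 and 6.497 ± 0.523 TPM, and the folate receptor gene FOLR1 at 211.1 ± 20.3 and 213.9 ± 8.0 TPM (adjusted p = 0.583, 0.0868 and 0.853). FPGS, which adds glutamates to folates and MTX, and GGH, which removes them, had log2 fold changes of -0.16 and 0.08 (adjusted p = 0.174 and 0.262). Of 7 tested members of the uptake and polyglutamation list none rose and SLCO1A2 alone fell, adjusted over the list alone as well (log2 fold change -0.71, adjusted p = 0.0256), a call lost with no filter (0.0955) and without parental library 2 (0.0822), parental library 3 (0.0670), resistant library 1 (0.0792) or resistant library 2 (0.0513). TYMS, the thymidylate synthase gene, had a log2 fold change of -0.12 (adjusted p = 0.115), with 43.0% of its sequences of 31 bases shared, and ATIC one of -0.20 (0.0627, or 0.0205 without resistant library 2 and 0.0414 with median-ratio scaling). Among 8 tested drug efflux genes 1 rose and 3 fell, or 1 and 4 adjusted over the list alone. ABCG2, an exporter that carries MTX, rose from 41.7 ± 3.34 to 56.8 ± 2.67 TPM, and ABCA2 and ABCC5 fell by 1.07 and fell by 0.50 on the log2 scale. ABCC10 had a log2 fold change of -0.37 (adjusted p = 0.0208, but 0.0648 with the batch number as a term, 0.0753 without parental library 1, and 0.0677, 0.0503 and 0.0574 without resistant libraries 1, 2 and 3). ABCC1, ABCC2 and ABCC4 had log2 fold changes of -0.24, 0.36 and -0.29 (adjusted p = 0.0579, 0.169 and 0.339, with 0.0350 for ABCC1 without resistant library 3 and 0.0483 with quantile normalization). ABCC3 (0.933 and 0.626 TPM) and ABCB1 (0.685 and 1.31 TPM) were below the filter.

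Of 19 tested enzymes of the folate cycle, 4 were higher and 1 was lower, over all genes and adjusted over the list alone, and without resistant library 1 the higher ones were 2. Besides DHFR they were MTHFS, at 13.2 ± 0.272 and 18.2 ± 0.788 TPM, GLDC, at 186.1 ± 13 and 221.0 ± 6.31 TPM, and MTHFR, at 1.70 ± 0.220 and 2.81 ± 0.499 TPM. GLDC (adjusted p = 0.0173) was not called without resistant library 1 (0.0679) or without the variance trend (0.0537). MTHFR (0.0393) was not called with the batch number as a term (0.0582), with no filter (0.0872), with quantile normalization (0.0567) or without any 1 library (0.0602, 0.108 and 0.0791 without parental libraries 1, 2 and 3, and 0.136, 0.0736 and 0.0558 without resistant libraries 1, 2 and 3). MTHFD2, the mitochondrial enzyme, fell from 117.5 ± 4.82 to 94.95 ± 4.95 TPM. The list was not shifted (camera adjusted p = 0.963), and its median of -0.06 and mean of 0.27 differ in sign. Among 22 tested genes of pyrimidine and deoxynucleotide supply, none rose and 3 fell, with the same counts adjusted over the list alone. They were RRM2 and RRM1, the ribonucleotide reductase subunits, from 503.6 ± 18 to 304.9 ± 14 TPM and from 79.3 ± 2.26 to 62.3 ± 2.25 TPM, and SAMHD1, which breaks down deoxynucleotides, from 5.35 ± 0.926 to 2.69 ± 0.371 TPM. This list was not shifted either (adjusted p = 0.176).

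In the hCG beta cluster on chromosome 19, 4 genes fell. CGB5 (49043884 to 49045311) fell from 169.6 ± 17.9 to 19.9 ± 3.13 TPM and CGB8 (49047638 to 49049106) from 110.5 ± 18.6 to 23.2 ± 4.29 TPM (adjusted p = 1.72e-06 and 4.56e-05). CGB3 and CGB2 fell by 1.67 and fell by 1.52 on the log2 scale. These genes share 73.4% to 92.5% of their sequences of 31 bases with other genes, so the division of TPM among them is uncertain. Their sum with CGB1 and CGB7 was 306.8 ± 41.6 TPM in parental and 50.5 ± 5.65 TPM in resistant cells, 6.08-fold lower (exact two-sided permutation p = 0.1, the smallest possible for 3 against 3 libraries). CGA, the gene of the shared alpha subunit on chromosome 6, went from 251.6 ± 27.3 to 175.3 ± 36.3 TPM (adjusted p = 0.0232), a call lost with no filter (0.0949), without the variance trend (0.0535), and without parental library 1 (0.0585), parental library 3 (0.0621), resistant library 1 (0.0769) or resistant library 3 (0.0681). Other markers of syncytiotrophoblast, the fused hormone-making layer of the placenta, had smaller differences, such as the fusogen gene ERVW-1 and the regulator gene GCM1 with log2 fold changes of -0.06 and -0.18, neither past the test and both chosen after their values were seen. Of 37 tested genes of this list 2 were higher and 8 lower, or 3 and 9 adjusted over the list alone. The higher were 1 without parental library 1, and the lower were 5 without parental library 1 or resistant library 3. The list was not shifted (median -0.09, camera adjusted p = 0.0689), but passed with the batch number as a term (0.0443), with a mean of at least 5 TPM (0.0310), with the genes of the shifted bins left out (0.0206), an alternative added after seeing the data, with fry (0.0304), without parental library 1 (0.0167) and without resistant library 2 (0.0305), with adjusted p = 0.650 with an estimated correlation.

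**Figure D4:**
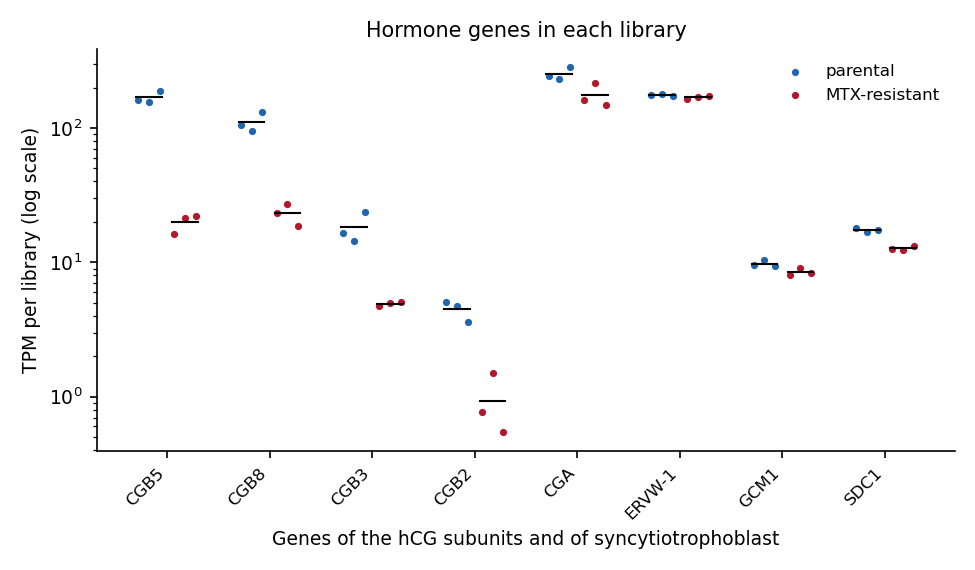
TPM of genes of the hCG subunits and of syncytiotrophoblast in each library (log scale), with parental libraries in blue, resistant libraries in red and a bar at the mean of each group. CGB5 and CGB8 are lower in all 3 resistant libraries, while ERVW-1 and GCM1 lie close together in both groups.

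Genes of cytotrophoblast, the proliferating progenitor layer, moved both ways. Of 29 tested members 12 rose and 7 fell, or 12 and 8 adjusted over the list alone, and the fallen ones were 4 without parental library 1, 2 or 3. TP63, a regulator of epithelial progenitors, rose from 14.6 ± 1.70 to 29.98 ± 1.69 TPM and the endocytic receptor gene LRP2 from 4.995 ± 0.365 to 11.5 ± 0.262 TPM. SMAGP rose by 0.56 on the log2 scale. The list was not shifted (median 0.01, camera adjusted p = 0.524).

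Genes of epithelial junctions rose more often than they fell. Of 30 tested members 9 rose and 2 fell, or 13 and 2 adjusted over the list alone, and the fallen ones were 0 without resistant library 2 or 3 and 1 without parental library 1, 2 or 3. CDH1, the E-cadherin gene, rose from 296.3 ± 10.6 to 417.2 ± 13.4 TPM, EPCAM from 226.5 ± 5.14 to 311.6 ± 14.1 TPM, SPINT1 from 154.7 ± 5.0 to 203.4 ± 2.25 TPM, and OCLN, which lies on the rising part of chromosome 5, from 11.6 ± 1.05 to 21.6 ± 1.88 TPM. As a set, these genes were shifted up (median 0.20, camera adjusted p = 0.00275, with adjusted p = 0.650 with an estimated correlation). Mesenchymal genes moved both ways, with 5 of 16 higher and 5 lower over all genes and adjusted over the list alone, and were not shifted (adjusted p = 0.963). MMP14, a membrane matrix protease gene, rose from 463.5 ± 11.8 to 705.6 ± 5.77 TPM and TPM1 by 0.52 on the log2 scale, while SPARC, FN1 and the secreted protease gene MMP2 fell, the last from 357.3 ± 18.8 to 224.7 ± 12.3 TPM.

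Of 34 tested genes of glycolysis and the hypoxia response 22 fell and 1 rose, or 26 and 2 adjusted over the list alone, with a median log2 fold change of -0.27. Leaving out 1 library gave 0 risers, except without parental library 2 (1) or 3 (2). LDHB, on chromosome 12, fell from 2555 ± 23.4 to 1615 ± 26.5 TPM, HK2, the hexokinase gene, from 133.3 ± 18.1 to 72.4 ± 11.4 TPM, PFKFB4 from 133.6 ± 7.15 to 78.7 ± 8.94 TPM and PGAM1 from 1075 ± 21 to 878.4 ± 19 TPM. Camera shifted the list down (adjusted p = 6.03e-09, with adjusted p = 0.644 with an estimated correlation). Of 72 tested genes of the nuclear-encoded respiratory chain 34 fell and 2 rose (1 without parental library 1 or resistant library 1), or 40 and 2 adjusted over the list alone, with a median of -0.17. ATP5MC2 fell from 1489 ± 32.8 to 969.5 ± 16.3 TPM, UQCRQ, on chromosome 5, from 266.8 ± 14.9 to 162.7 ± 12.8 TPM, and NDUFB5 from 195.9 ± 4.15 to 139.9 ± 7.0 TPM. This list was shifted down (camera adjusted p = 3.80e-10, with adjusted p = 0.644 with an estimated correlation).

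The 13 mitochondrially encoded genes of the chain were all higher on average in resistant cells, with a median log2 fold change of 0.58, but varied widely between libraries. Of them 3 rose over all genes, and 9 adjusted over the list alone. MT-ND1 went from 1009 ± 342 to 2363 ± 654 TPM (adjusted p = 0.00960, or 0.0570 with no filter). The count of 3 was 1 without parental library 1 or 2 or resistant library 2 or 3, 6 without resistant library 1 and 11 without parental library 3. The summed TPM of the 13 genes did not separate the groups (exact two-sided permutation p = 0.2, where 0.1 is the smallest possible). Camera shifted this set up (adjusted p = 0.00229, with adjusted p = 0.707 with an estimated correlation).

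Among cell cycle genes more members fell than rose. Of 36 tested genes of mitosis 15 fell and 1 rose (0 without any 1 library other than parental library 3), or 15 and 2 adjusted over the list alone, with a median of -0.16. The kinase gene AURKA, on chromosome 20, fell from 110.9 ± 7.22 to 72.6 ± 1.35 TPM, AURKB from 101.1 ± 4.54 to 76.0 ± 0.533 TPM, KIF2C from 70.6 ± 3.27 to 51.1 ± 1.37 TPM and TPX2, also on chromosome 20, from 124.4 ± 4.35 to 93.6 ± 1.37 TPM. Mitosis genes were shifted down as a set (camera adjusted p = 6.86e-06, with adjusted p = 0.644 with an estimated correlation). Of 41 tested genes of the start of replication 11 fell and none rose, or 12 and 1 adjusted over the list alone, and the fallen ones were 7 without any 1 library other than parental library 3, without which 1 rose. RFC4, a subunit of the clamp loader, and E2F1 fell by 0.60 and fell by 0.44 on the log2 scale. This list was shifted down (median -0.08, camera adjusted p = 0.0168, 0.0814 without resistant library 3, with adjusted p = 0.707 with an estimated correlation). Of 48 listed replication-dependent histone genes only 20 were tested, and the highest mean over the 6 libraries was 32.3 TPM (H1-2). Of the 20 tested, 8 fell and 2 rose, or 9 and 3 adjusted over the list alone. H2BC5 fell from 40.5 ± 2.51 to 15.1 ± 2.91 TPM and H2BC11 from 20.01 ± 2.32 to 8.29 ± 2.15 TPM. The histone list was shifted down (median -0.29, camera adjusted p = 0.0242, 0.0911 without parental library 2, with adjusted p = 0.644 with an estimated correlation). This call was also lost with no filter and with a mean of at least 5 TPM.

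Cholesterol and ribosomal protein genes shifted in opposite directions. Of 23 tested genes of cholesterol synthesis 6 rose and 2 fell, with the same counts adjusted over the list alone, and 1 fell when any 1 library was left out. FDFT1, the squalene synthase gene, rose from 7.97 ± 0.626 to 19.5 ± 4.8 TPM, and SC5D and TM7SF2 rose by 0.48 and rose by 0.73 on the log2 scale. STARD4, on the lower part of chromosome 5, fell from 47.9 ± 3.50 to 29.2 ± 2.52 TPM. The list was shifted up (median 0.11, camera adjusted p = 0.0388, with adjusted p = 0.707 with an estimated correlation), a call lost without parental library 1 (0.0977), parental library 2 (0.0871) or resistant library 3 (0.109). It was also lost without the variance trend (0.0678) and with fry (0.0880). Of 76 tested ribosomal protein genes 10 fell and 2 rose, or 6 and 2 adjusted over the list alone. RPS21, RPL35A and RPL12 fell by 0.45, fell by 0.37 and fell by 0.36 on the log2 scale, while RPS23 of the DHFR region rose by 2.20. The count of 10 was 3, 5 and 18 without parental libraries 1, 2 and 3, and 4, 5 and 4 without resistant libraries 1, 2 and 3. The list was shifted down (median -0.10, camera adjusted p = 1.86e-05, with adjusted p = 0.707 with an estimated correlation), a call lost with quantile normalization.

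**Figure D5:**
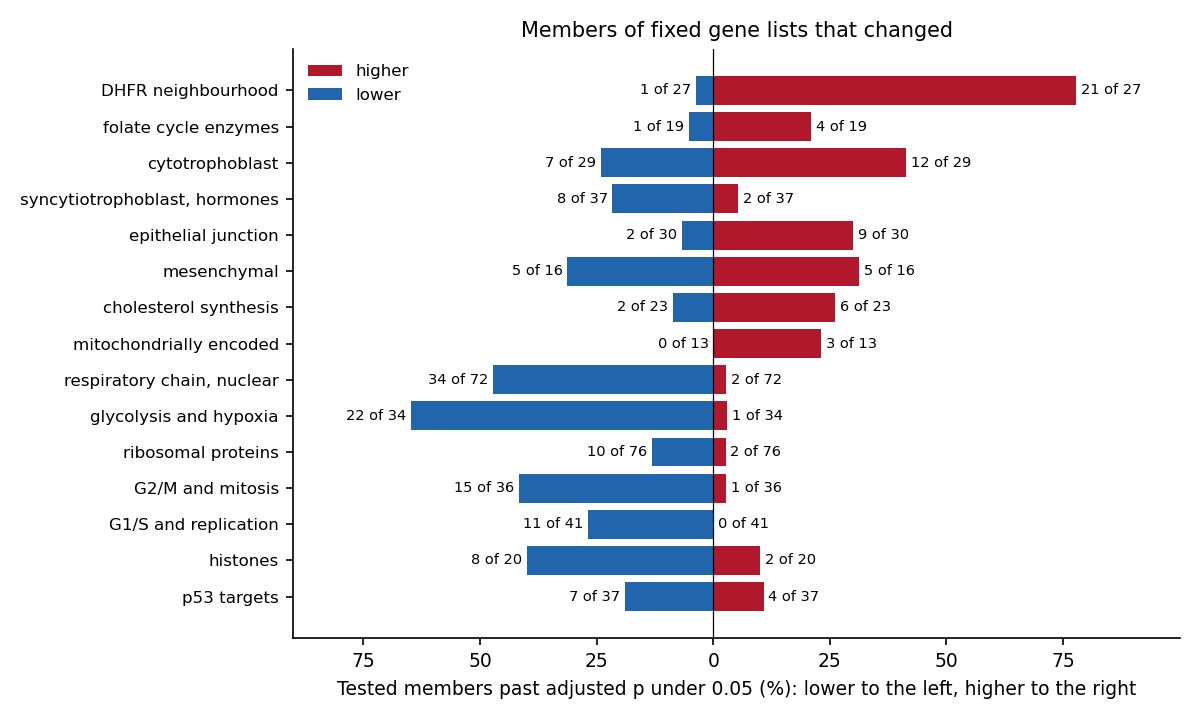
Share of the tested members of 15 gene lists that were lower (blue, to the left) or higher (red, to the right) at an adjusted p under 0.05, in percent, with the counts beside the bars. Genes around DHFR stand out to the right (21 of 27), and those of glycolysis (22 of 34) and the respiratory chain (34 of 72) to the left.

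Targets of the tumour suppressor p53 were not shifted (median -0.04, camera adjusted p = 0.316). Of 37 tested members 4 rose and 7 fell, or 4 and 8 adjusted over the list alone. Besides MDM2, CCNG1 fell by 0.26 on the log2 scale, and the decoy receptor gene TNFRSF10C and the ceramidase gene ACER2 rose by 0.47 and rose by 0.57. The count of 7 was 2 without parental library 1 or resistant library 3, 3 without resistant library 1, and 4 without parental library 2 or resistant library 2.

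Of the 45 tested lists, 10 were shifted by camera, 4 up and 6 down. None was shifted with an estimated correlation, with 4235 genes at an unadjusted limma p under 0.05, and 22 were shifted by fry, which tests the members' direction without comparing them with other genes.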

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

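The tests of reads shared with near-identical genes in the DHFR segment and of the neighbourhood of the hCG beta genes were set before their results were seen. The DHFR segment itself was drawn after its rise was seen. The other tests of this part were chosen only after the result was seen.

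Transcripts without a gene symbol were not part of the comparison of genes, and 3 of the 470 tested changed at least 2-fold in resistant cells (2 higher and 1 lower, with 85 at an unadjusted limma p under 0.05). ENST00000537570, a processed pseudogene on chromosome 12 at 68841946 to 68842384, within the bounds of MDM2, fell from 259.3 ± 15.3 to 111.0 ± 7.72 TPM. ENST00000492984, a pseudogene on chromosome 5 at 80855507 to 80855843, within the bounds of MSH3, rose from 0.195 ± 0.337 to 4.03 ± 0.358 TPM. ENST00000488511, a pseudogene on chromosome 14 at 76968683 to 76969145, rose from 0.0718 ± 0.124 to 3.22 ± 0.758 TPM.

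All 14 tested genes from FAM151B to HAPLN1 on chromosome 5 were higher in resistant cells (13 without parental library 1 or 3 or resistant library 1 or 2, where FAM151B did not pass). CKMT2, XRCC4, HAPLN1 and DBIP2 share 0% of their sequences of 31 bases with other genes. Their log2 fold changes of 2.77, 1.74, 1.21 and 3.53 argue against reads shared with near-identical genes elsewhere as the cause for these genes. The median of 1.74 over the 7 genes with under 5% shared is no test of the segment. Its bounds were drawn around the rise, and 13 of its 14 genes rose at least 2-fold, so that a median over 1 was fixed. Scaling between libraries, which moves all genes of a library alike, is argued against by the median of 0.0140 over the tested genes outside the segment. A candidate explanation is a set of extra copies of the segment in the resistant cells, nested around DHFR, with a fold that declines from DHFR towards the telomere. The decline (Spearman's rho -0.94 across 12 genes) was seen before this was put forward and within bounds drawn around the rise, so it does not decide between extra copies and a regional activation, and no DNA was measured. The cells may also have had more copies of 5q before DHFR, from 50 to 80.5 Mb (median 0.31), and fewer beyond 84 Mb (median -0.33), which was not tested either.

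Genes at 64 to 86 Mb of chromosome 12 fell in part, MDM2 among them, with others such as CPSF6 between them at their parental level within the spread. Scaling is argued against by the median of 0.0156 over the tested genes outside the window. The 60 window genes outside the p53 list had a median of -0.56. This does not decide whether a lower output of p53 caused the whole block. The window was drawn around the fall, nearly all of its genes lie outside that list, and the list need not hold every target. A candidate explanation is extra copies of part of the window in parental cells, fewer in the resistant cells. Parental TPM and log2 fold change had a Spearman's rho of -0.62 across the 61 genes, against a median of -0.22 over 124 windows of 22 Mb on other chromosomes, of which 0.806% were as low, which does not decide it, because those windows were not matched for a fall, the parental level is part of the fold and falls at low TPM are understated. Whether MDM2 itself also follows p53 stays open, as do copies, which RNA does not count.

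4 genes of the hCG beta subunit fell while most other hormone and fusion genes of the trophoblast did not pass the test. A shift of reads among the summed hCG beta genes is argued against by their sum, with a log2 fold change of -2.58. The sum does not cover reads shared with genes outside it. A fall of the whole neighbourhood is argued against by the median of 0.0689 over the 67 other tested genes within 1 Mb. A general fall of syncytiotrophoblast genes of about the same size is argued against by the median of -0.0755 (SD 0.307) of the 31 other tested members of that list, of which 2 were higher and 4 lower. Regulation of the beta genes in particular, or the outgrowth of cells that made less hCG during selection, may each account for the fall, and no value here separates them.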

How the results depend on the processing

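No test in this part was chosen after the result was seen, except the alternatives for genes named outside the rule and leaving the genes of the shifted bins out of the lists, which gave 12 shifted lists: 9 of the 10, without the DHFR neighbourhood, which could no longer be tested, and also syncytiotrophoblast (0.0206), WNT targets (0.0439, against 0.0736) and lysosome (0.0439). DHFR kept its direction and its call under every alternative, with a log2 fold change of 4.90 to 5.08 over the processing alternatives and 4.99 to 5.09 when 1 library was left out. The counts at 2-fold moved with the pseudocount by construction, because it shrinks folds at low TPM: with 0.1 in place of 1 they were 290 in all, 169 higher and 121 lower, and with 5 they were 57, 30 and 27. With a mean of at least 5 TPM fewer genes were tested, and 99 passed, 57 higher and 42 lower. Leaving out 1 library gave 789 to 1384 genes higher at any size (887 without parental library 1 and 789 without resistant library 1) and 851 to 1214 lower (851 without parental library 1). The batch number as a term gave 174 genes at 2-fold, 169 of them among the 170, and 27 bins, and it changed no call of a list other than syncytiotrophoblast (0.0443); of the genes named in the text it ended the calls of MTHFR and ABCC10. With an estimated correlation, camera shifted 0 lists and 0 bins, with 4235 genes at an unadjusted limma p under 0.05. Adjusted p was then 0.106 for the DHFR neighbourhood, 0.644 for mitosis, glycolysis, the respiratory chain and histones, 0.650 for epithelial junctions, and 0.707 for replication, cholesterol, mitochondrially encoded and ribosomal protein genes. In each of the 10 shifted lists the estimated correlation was above the preset of 0.01, from 0.0538 (DHFR neighbourhood) to 0.775 (mitochondrially encoded). Camera allows a set more variance at a higher correlation. How much of the loss of calls this accounts for was not tested, and it cannot be the only difference between the 2 settings. The unadjusted camera p also rose for MHC class I presentation, from 0.0222 to 0.0753, where the estimated correlation of -0.0216 was below the preset. It did not rise in every such list (0.490 and 0.489 for the unfolded protein response). Fry shifted 22 lists, but not replication (0.0756), cholesterol (0.0880), mitochondrially encoded (0.156) or ribosomal protein genes (0.184). Among the lists called by fry and not by camera were cytotrophoblast (0.0137), p53 (0.0332) and deoxynucleotide supply (0.0245). It turned the direction of the folate cycle (0.0107, upward) and of DNA repair (0.0332, upward), where camera gave 0.963 and 0.649, downward, and called neither. In both lists the median (-0.06 and -0.04) and the mean (0.27 and 0.06) differ in sign, with 12 of 19 and 28 of 47 members negative. DHFR, with a log2 fold change of 5.04, is a member of the folate cycle list, and fry was not run on that list without it. Whether DHFR or the difference in sign accounts for the difference between fry and camera was not tested. Cholesterol was not called without the variance trend (0.0678), ribosomal proteins with quantile normalization (0.0503), and histones without a filter (0.0953) or with a mean of at least 5 TPM (0.0827); the cause was not tested. Without 1 library the adjusted p ranged from 0.00206 to 0.0814 for replication, from 0.00405 to 0.109 for cholesterol and from 0.00835 to 0.0911 for histones. Of the values under alternatives of genes named by the rule, 2819 were on their side of the threshold, 144 lost and 4 gained a call, among them losses without a filter for CGA (0.0949), MTHFR (0.0872), SLCO1A2 (0.0955) and MT-ND1 (0.0570), without the variance trend for CGA (0.0535) and GLDC (0.0537) and with quantile normalization for MTHFR (0.0567), and gains for ABCC1 with quantile normalization (0.0483) and ATIC with median-ratio scaling (0.0414). Of the tested genes named outside the rule, FAM151B lost its call with no filter (0.105) and without any of 4 libraries (0.0667 to 0.105), CGB1 gained one without parental library 2 (0.0106), and no other call changed. Unknown depth leaves open whether genes near 1 TPM rest on many reads or few.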

Other observations

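Genes of antigen presentation, the lysosome and the matrix had members that changed, while the calls of their lists depended on the setting. Of 10 tested genes of MHC class I presentation 5 fell and 1 rose, with the same counts adjusted over the list alone. TAP2, a peptide transporter subunit, fell from 5.52 ± 1.81 to 1.77 ± 0.142 TPM, and HLA-F from 10.6 ± 0.188 to 7.25 ± 0.50 TPM, while B2M rose from 2004 ± 36.4 to 2457 ± 137 TPM. The list was not shifted (camera adjusted p = 0.0768), but passed without resistant library 3 (0.0433), with no filter (0.0388) and with fry (0.00969), and its adjusted p was 0.644 with an estimated correlation. Of 31 tested lysosome genes 6 rose and 4 fell, or 7 and 4 adjusted over the list alone, and the fallen ones were 2 without parental library 2 or 3 or resistant library 1 or 3. HEXB, on the rising part of chromosome 5, rose from 106.2 ± 9.96 to 172.6 ± 3.75 TPM and NPC2 from 340.3 ± 4.83 to 446.5 ± 15.4 TPM (camera adjusted p = 0.129 for the list, but 0.0331 with quantile normalization, 0.0439 with the genes of the shifted bins left out and 0.0137 with fry). LIPA, which on the log2(TPM + 1) scale fell most of the genes named here, is also a lysosomal enzyme gene. Of 19 tested matrix genes 7 rose and 3 fell, with the same counts adjusted over the list alone, and those that rose were 4 without parental library 2 or resistant library 1 or 3. COL6A3 rose from 8.06 ± 0.216 to 18.9 ± 2.16 TPM and TIMP1 fell from 4.41 ± 0.967 to 1.87 ± 0.343 TPM (camera adjusted p = 0.316, and 0.0145 with fry).

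Stress and signalling genes went both ways as well. Of 36 tested genes of the amino acid response 5 rose and 8 fell, or 6 and 8 adjusted over the list alone. STC2, on the lower part of chromosome 5, fell from 445.6 ± 59.0 to 247.8 ± 12 TPM, and CEBPB from 104.0 ± 14.8 to 68.4 ± 5.82 TPM. Those that rose were 2 without resistant library 2 and 3 without parental library 1 or 2 or resistant library 1 or 3. The list was not shifted (camera adjusted p = 0.649). Of 18 tested genes of the TGF-beta and BMP response 7 rose and 1 fell, or 10 and 3 adjusted over the list alone, and those that rose were 4 without parental library 2 and 3 without resistant library 1 or 3, while 2 fell without parental library 1. FST, the follistatin gene, rose from 1.63 ± 0.237 to 3.92 ± 0.662 TPM and ID2 fell from 16.7 ± 2.46 to 9.68 ± 1.44 TPM (camera adjusted p = 0.191 for the list, and 0.00969 with fry).

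Markers of other cell types were mostly low. The highest mean over the 6 libraries was 4.27 TPM for fibroblast markers (COL1A1), 3.73 TPM for leukocyte markers (CD68), 30.6 TPM for endothelial markers (EGFL7), 33.1 TPM for erythroid markers (HBE1) and 90.8 TPM for markers of cervical or kidney lines (SFN). Both tested globin genes fell, HBE1 from 41.7 to 24.6 TPM and HBG2 from 5.48 to 2.10 TPM, and SFN rose from 69.6 to 112 TPM. These lists had fewer than 5 tested members and were not tested as sets.

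Leaving out the shifted bins was added after the data were seen, and the bins were picked by their shift in these data. The prediction for the respiratory chain was written before its own result was seen. The counts over other splits were chosen after theirs. The small falls of respiratory chain genes might come from members that lie in the falling parts of chromosomes 5, 12 and 20. Without the genes of the shifted bins the list was still shifted by camera (adjusted p = 4.91e-11, against 3.80e-10 with them, and 0.644 with an estimated correlation), which argues against their location as the whole cause.

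The 6 libraries can be split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 170 genes changed at least 2-fold, and the highest of the other splits gave 0. Every other split puts libraries of both groups on each side. The difference between the groups then adds to the spread within a side and remains in part between the sides, so these counts are no measure of chance. It gave 10 shifted lists against at most 9, and 25 shifted bins against at most 20, so that the real split was the only 1 of the 10 with as large a result in each case. Of the other splits, 3 also part all 3 batch pairs, and these gave at most 7 lists and 9 bins.

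The rise of the DHFR region and the falls on 12q and 20q may be followed up by measuring DNA. If the fold of 33.8 for DHFR came from copies, DNA of the resistant cells would show extra copies with a nested edge near HAPLN1, in which the decline with distance in RNA (rho -0.94) would be seen in copy number too.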
